A study of Mus musculus with 49 samples.

How the data were processed

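Optic nerve heads of mice labelled female were punched out, and total RNA of each was labelled and hybridised to 1 array, 49 arrays in all. Groups were taken from the labels for strain, radiation and age: 9 arrays of D2-Gpnmb+ and 20 of untreated DBA/2J at 8.5 months, and 10 each of irradiated DBA/2J at 8.5 and at 10.5 months. Codes in the sample names (B, B1, B2, B3, C3, C4 and C5) were treated as possible batches, though the labels do not say what they stand for. Titles also sort arrays into clusters that the submitters made from these data, so the clusters served no test.

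The deposited tables hold log2 values of 45101 probe sets per array, summarised by the authors with RMA; the labels name GCOS, RMA and the affy package with no versions. The authors quantile-normalised all optic nerve head arrays of their study together, and 30 of those arrays belong to another series and were not used. They left out 1 D2-Gpnmb+ array after quality control. The log scale was checked on the values, which ran from 2.0 to 13.81 with array medians from 4.87 to 5.04 and correlations between arrays from 0.961 to 0.995; base 2 follows from RMA. A further deposited table held equal values for the 49 arrays (largest difference 0.0), so exchanging the tables tested nothing. Array data have no counts, and the number of arrays limits the precision.

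Probe sets were matched to genes through the annotation supplied with the data: 34945 had 1 gene symbol, 932 had several, 9160 had none, and 64 were controls. Each gene was represented by the probe set with 1 symbol and the highest mean over all 49 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied. A group-means model was fitted with lmFit and moderated with eBayes in limma 3.58.1 under R 4.3.3 (residual df 45, prior df 3.51), and p-values were adjusted by Benjamini and Hochberg over genes within each comparison, with 0.05 as the threshold. The 5 comparisons were untreated DBA/2J against D2-Gpnmb+, irradiated against untreated DBA/2J and irradiated DBA/2J against D2-Gpnmb+ at 8.5 months, irradiated DBA/2J at 10.5 against 8.5 months, and irradiated DBA/2J at 10.5 months against D2-Gpnmb+ at 8.5 months. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served the other tests and the plots.

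The groups, comparisons, tests, 41 gene lists and alternative settings were fixed before the data were examined. Lists were tested for a shift in 1 direction with fry, adjusted over the 41 lists within a comparison, and again with camera under an estimated and under a preset correlation of 0.01; 86 list symbols had no matching gene. Genes were named by a rule set at the same time: the 10 higher and 10 lower passing genes with the largest log2 differences (clone-like names left out), up to 4 passing members of each list described or 2 where none passed, and Gpnmb, Itgam, Glycam1 and Edn2 throughout. Further probe sets of Kdm5d and Eif2s3y were named after their values were seen. Permutation tests were two-sided, exact where a group held 9 arrays and for 10 against 10, otherwise with 100000 resamples. Correlation between strain and radiation effects was set against 100 simulated sets of unchanged groups with the same shared arrays and against 100 random divisions of the shared arrays.

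The calls were tested on simulated data with planted changes. Of genes changed 1.25-fold 36 to 68% were called, of those changed 1.5-fold 86 to 92%, and of those changed 2-fold 98 to 100%. There were 8 to 15 false calls among 18193 genes. The simulated noise was drawn independently for each gene, with no effect of name codes. These rates therefore do not measure false calls in the real arrays, where genes vary together. Alternatives covered scaling (quantile normalization over the 49 arrays alone, centring on array medians), the choice of probe set, filters on dim genes, the arrays in the fit, array weights, a trended robust variance, the name code as a random block, covariates for RNA quality and for photoreceptor genes, stricter thresholds, single name codes, and each array left out in turn. With centring, the median difference of all genes lay within 0.06 of 0 in each comparison. Covariates for skeletal muscle genes and a fit without 2 irradiated arrays were chosen after seeing the data.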

Results

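RNA of the mouse optic nerve head, where ganglion cell axons leave the eye, was measured on 49 whole-transcriptome arrays, each from a punched-out nerve head. The arrays fell into 4 groups of mice labelled female. DBA/2J-Gpnmb+ mice (here D2-Gpnmb+), a DBA/2J line with an intact Gpnmb gene used as the control, gave 9 arrays at 8.5 months. DBA/2J mice, which develop an inherited glaucoma, gave 20 arrays without radiation at 8.5 months, 10 arrays after radiation at 8.5 months and 10 after radiation at 10.5 months. Values were log2 signals between 2.0 and 13.81, and the array medians lay between 4.87 and 5.04. The number of arrays limits the precision, and no counts lie behind a signal. Because the labels do not say whether arrays came from separate animals, each p measures the spread between samples.

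Gpnmb, a glycoprotein of melanosomes and macrophages that carries a nonsense mutation in DBA/2J, separated the strains. Its signal was 9.16 ± 0.40 (SD, n = 9) in D2-Gpnmb+ and 7.20 ± 0.43 (SD, n = 20) in untreated DBA/2J, a fall of 3.9-fold (adjusted p = 5.1e-13, limma). All 20 untreated DBA/2J arrays lay below every D2-Gpnmb+ array. The gene's other probe set was 7.64-fold lower. Signals in irradiated DBA/2J were 7.03 ± 0.35 at 8.5 months and 6.61 ± 0.46 at 10.5 months (SD, n = 10 each). Xist, the RNA that silences the second X chromosome of females, stood at 11.42 to 11.48 in the 4 group means. Of the Y-linked genes, Eif2s3y had a probe set with group means between 2.37 and 2.41 at 8.5 months and a mean of 5.92 ± 0.74 (SD, n = 10) in the irradiated 10.5-month arrays.

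**Figure D1:**
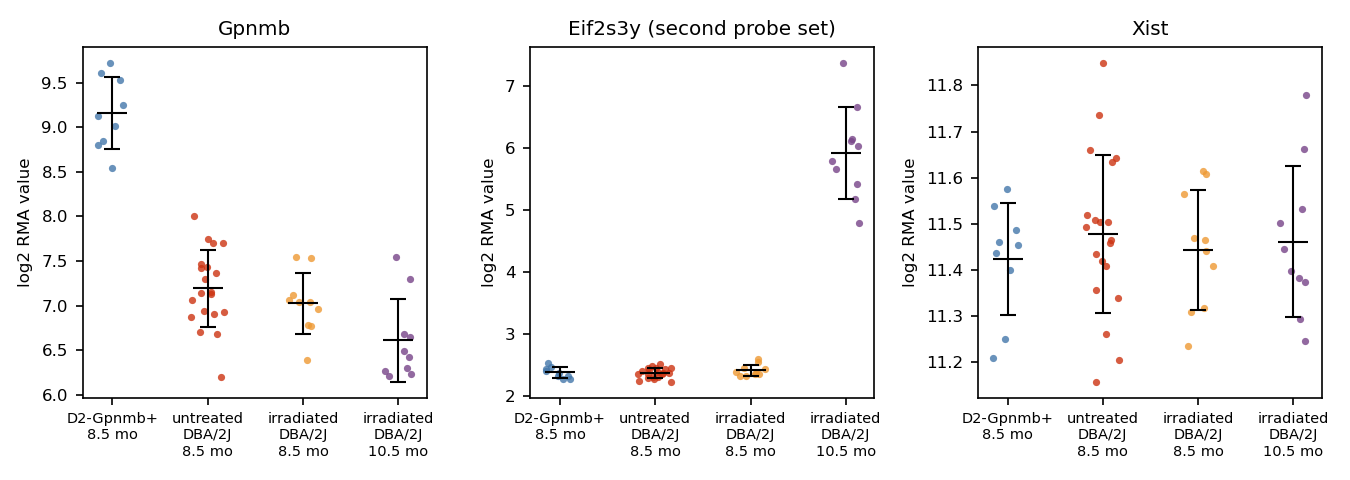
Log2 signal of Gpnmb, of the Eif2s3y probe set that rose and of Xist in each of the 49 arrays, by group; bars give the mean and SD. Gpnmb separated the strains, and Eif2s3y was raised in the irradiated 10.5-month arrays alone (4.79 to 7.37), with Xist near 11.4 in all groups.

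Untreated DBA/2J was compared with D2-Gpnmb+ at 8.5 months to ask what the glaucoma-prone strain changes in the optic nerve head. Orm1, Il7r and Il1rn were among the genes that rose most in DBA/2J, and the pigment list was lower. Orm1, an acute-phase plasma protein, rose 4.98-fold from 6.71 ± 0.70 (SD, n = 9) to 9.03 ± 0.53 (SD, n = 20), and all 20 DBA/2J arrays lay above every control array. Pmel, which builds the fibrils of melanosomes, fell by 3.87 on the log2 scale (SE 0.29), or 14.6-fold. Of 18193 genes, 509 passed an adjusted p of 0.05 in limma, 311 higher and 198 lower, and 211 of these differed by at least 1.5-fold.

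Il7r, a cytokine receptor of lymphocytes, rose by 2.14 (SE 0.16), and Lcn2, an iron-withholding protein of neutrophils and reactive astrocytes, also by 2.14 but with a wider error (SE 0.45). Il1rn, the natural antagonist of the interleukin-1 receptor, rose by 2.02 (SE 0.18), and Il6 by 1.89 (SE 0.46, adjusted p = 0.01). With the DBA/2J arrays whose names begin with B3 alone, the adjusted p of Il6 was 0.066. Rnf128, an ubiquitin ligase of T cells, rose by 1.82 and the receptor gene Cd200r4 by 1.74. Atp6v0d2, a subunit of the vacuolar proton pump, rose by 1.64, the neuropeptide gene Npy by 1.62, and Itgb2, the shared beta chain of leukocyte integrins, by 1.56 (SE 0.17). In each of these genes except Il6 (19 arrays), all 20 DBA/2J arrays lay above the control mean.

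Pigment cells gave most of the largest falls. Of the 20 measured genes of the pigment epithelium and melanocyte list, 12 fell, none rose and 8 did not pass; adjusted over the list alone, 14 fell. The list was lower as a whole (fry adjusted p = 9e-13; adjusted p = 3.88e-05 with an estimated correlation). Besides Pmel, the melanosomal gene Mlana fell by 3.44 (SE 0.30). Tyrp1, which acts in melanin synthesis, fell by 3.43 (SE 0.24) and the synthesis gene Dct by 2.28 (SE 0.15). Outside the enzymes, Trpm1, a channel of melanocytes and bipolar cells, fell by 2.37, the melanosome transport gene Mlph by 2.22, the transporter gene Slc45a2 by 2.14 and the endolysosomal channel gene Mcoln3 by 2.13. Car6, a secreted carbonic anhydrase, fell by 2.38 (SE 0.19).

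**Figure D2:**
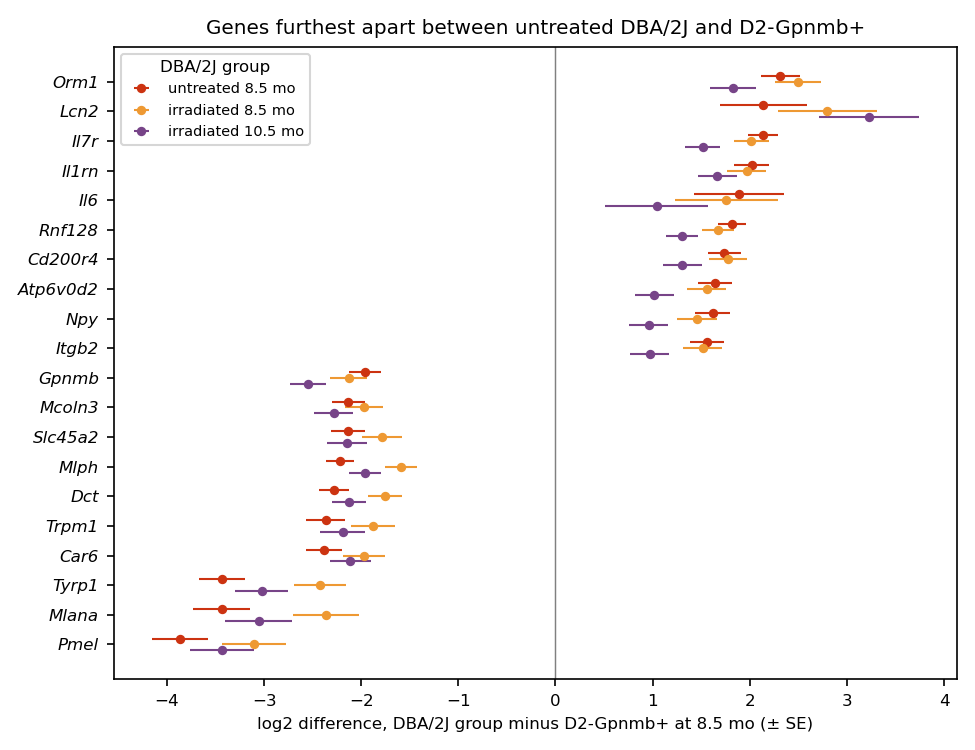
Log2 difference from D2-Gpnmb+ at 8.5 months of the 20 genes with the largest changes between untreated DBA/2J and D2-Gpnmb+, for untreated (n = 20), irradiated 8.5-month (n = 10) and irradiated 10.5-month (n = 10) DBA/2J; bars give the SE from limma. Orm1 was 2.32, 2.5 and 1.83 above D2-Gpnmb+ and Pmel was at -3.87, -3.11 and -3.44.

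Of the lists of myeloid cells, those of monocytes and macrophages and of phagocytic microglia were higher in untreated DBA/2J, while the microglia list (fry adjusted p = 0.0934) and the neutrophil and mast cell list (0.808) did not pass. In the monocyte and macrophage list 10 of 28 genes rose and none fell (fry adjusted p = 0.0174; adjusted p = 0.273 with an estimated correlation), among them the lectin gene Lgals3 by 1.45, the integrin gene Itgax by 1.34 and the lysosomal marker Cd68 by 1.29. In the list of phagocytic and disease-associated microglia 8 of 21 rose and Gpnmb itself fell (fry adjusted p = 0.0276; adjusted p = 0.273 with an estimated correlation); the fungal receptor gene Clec7a rose by 1.3 and Tyrobp, the signalling adaptor of microglial receptors, by 1.02. Of the T and NK cell list, Il7r and Ms4a4b (1.16) rose among 19 genes (fry adjusted p = 0.0182; adjusted p = 0.273 with an estimated correlation). Without array B10 of D2-Gpnmb+ these 3 lists had adjusted p of 0.061, 0.085 and 0.061; without array B6 the last 2 had 0.079 and 0.054, and without B1.5 and B1.3 the microglial list had 0.08 and 0.055. With the DBA/2J arrays of code B2 alone the 3 lists had adjusted p of 0.47, 0.56 and 0.47, and with the mean of probe sets the microglial list had 0.068. The surface epithelium list was lower (fry adjusted p = 0.0174; adjusted p = 0.415 with an estimated correlation; 0.2 with code B2 alone), with 1 of 16 genes passing, the junction gene Cdh1, which fell by 1.27.

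Other lists held single genes that passed while the list as a whole did not. Of 21 complement genes 5 rose (fry adjusted p = 0.117), the same number as when adjusted over the list alone, with factor B (Cfb, 0.80) and the anaphylatoxin receptor C3ar1 (0.66) beside Itgb2 and Itgax. Of 40 genes of leukocyte adhesion and transendothelial migration 7 rose and none fell (fry adjusted p = 0.24), including the oxidase subunits Ncf4 (1.06), Cybb (0.92) and Ncf1 (0.74); adjusted over the list alone 12 rose and 3 fell. The study itself picked members of the complement, adhesion and endothelin lists from arrays such as these, so their counts and list tests are not independent evidence. Of 21 microglia genes 6 rose, though the list did not pass, among them Trem2 by 0.90 (SE 0.20). Of 25 genes of astrocyte reactivity 4 rose (fry adjusted p = 0.244), with the protease inhibitors Serpina3n (1.45) and Timp1 (1.3) after Lcn2. Mmp12, a macrophage elastase, rose by 1.49 and was 1 of 2 of 36 matrix genes to pass (fry adjusted p = 0.611). Hmox1, which degrades haem, rose by 0.85 while the detoxification genes Gsta4 and Nqo1 fell by 0.43 and 0.40. Of 20 oxidative stress genes 2 rose, 2 fell and 16 did not pass (fry adjusted p = 0.865). Sox10, a transcription factor of the neural crest and oligodendrocytes, fell by 1.13 (SE 0.13). With code B2 alone the calls of Cfb, C3ar1, Ncf1, Trem2, Hmox1 and Nqo1 were lost.

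The endothelium, photoreceptor and ganglion cell lists had no gene past the threshold in limma for this contrast. The 23 endothelium genes had a median of -0.15 (fry adjusted p = 0.24), and 3 of them fell when adjusted over the list alone and 2 with the photoreceptor covariate. Neither the 26 photoreceptor genes nor the 21 genes of ganglion cells and axons held any, and their fry adjusted p was 0.865 each. No interferon response gene passed among 28 (fry adjusted p = 0.281), though 2 rose with the photoreceptor covariate. The chemokine gene Cxcl10 differed by 1.1 (adjusted p = 0.11). Over all genes 2597 had an unadjusted p under 0.05 in this comparison. Among genes the study singled out, Itgam (the alpha chain of a complement receptor on myeloid cells) differed by 0.00 (adjusted p = 0.98), but its mean signal of 3.28 in both groups lay under the lower quartile of every array (lowest 3.29), so this does not show an unchanged transcript. Glycam1 (an adhesion ligand) differed by 0.65 (adjusted p = 0.31) and the vasoconstrictor peptide gene Edn2 by 0.49 (adjusted p = 0.48). Of the 20 DBA/2J arrays, 12 for Glycam1 and 10 for Edn2 lay above every control array. Edn2 had an SD of 0.91 in DBA/2J and 0.10 in the controls, whose mean was low (3.59). Control arrays carry other name codes (B and B1) than the untreated DBA/2J arrays (B2 and B3), and no code holds both strains; the labels do not say what the codes stand for. Array weights raised the count to 874, and code B2 alone lowered it to 211.

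**Figure D3:**
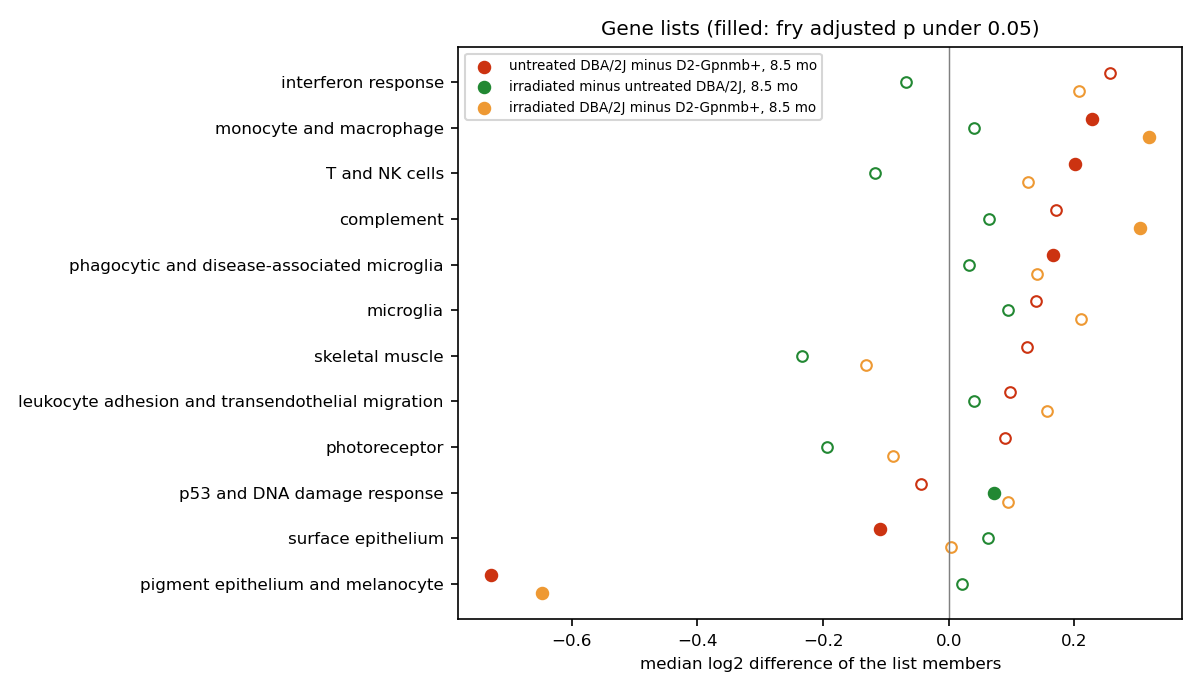
Median log2 difference of the measured members of 12 gene lists in the 3 comparisons at 8.5 months; filled points mark a fry adjusted p under 0.05. The pigment list had medians of -0.73 and -0.65 in untreated and irradiated DBA/2J against D2-Gpnmb+, and 0.02 between irradiated and untreated DBA/2J.

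Irradiated and untreated DBA/2J were compared at 8.5 months for what goes with radiation within the strain. The clearest gene was Cdkn1a, the p53 target that halts the cell cycle: it rose 1.93-fold, from 6.94 ± 0.38 (SD, n = 20) to 7.89 ± 0.45 (SD, n = 10), with adjusted p = 7.6e-05, and all 10 irradiated arrays lay above the untreated mean. Of 20 pigment genes 3 rose and 17 did not pass, Tyrp1 by 1.01 (SE 0.23), Mlana by 1.07 (SE 0.29) and Dct by 0.52 (a call that ended without any of 4 arrays); the list had a median of 0.02 (fry adjusted p = 0.784). Iglv1, an immunoglobulin light chain gene, fell by 1.65 (SE 0.40) and Jchain, which links antibody units, by 1.42 (SE 0.40). Jchain was the 1 gene to pass among 12 of the B cell and immunoglobulin list (fry adjusted p = 0.797), in which 2 rose and 2 fell when adjusted over the list alone. In all, limma gave 682 genes, 473 higher and 209 lower, most of them dim and little changed: 627 (91.9%) had a mean below the median of genes, the median absolute log2 difference was 0.306, and 49 reached 1.5-fold.

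Most of the other genes with large rises were near the low end of the signal range. Smr2, a salivary protein gene, went from 3.78 to 4.89, Cox8c, a testis form of a respiratory subunit, from 3.65 to 4.71, and the oocyte kinase gene Wee2 from 3.55 to 4.42. Tmco5 rose by 0.95 and the phospholipase gene Pla2g6 by 0.92, though 1 and 2 of their 3 probe sets differed the other way. At higher signal, the vasopressin receptor gene Avpr1a rose by 1.06 (8.53 in irradiated arrays) and Ecrg4 by 0.89 (9.34). Tmem91 fell by 0.75 (SE 0.16), the secreted protease inhibitor Slpi by 0.65 and the testis gene Brdt by 0.46 (2 of its 3 probe sets were lower). Genes among the 10 largest falls whose call ended without some single array were Cpsf4l and the clock gene Ciart (6 arrays each), Btnl9 (12), Mns1 (14) and Mipol1 (5). Only 2 of the 4 probe sets of Mipol1 were lower. Slpi passed no longer without C4.3 (adjusted p = 0.055) or C4.5 (0.056), Jchain without C3.6 (0.074), C4.3 (0.065), C4.5 (0.066), C3.2 (0.056) or C4.1 (0.058), Mlana without C3.10 (0.08) or C3.2 (0.056), and Ecrg4 without C3.8 (0.052).

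Among the 41 lists, those of p53 and of the sex check were called for irradiated against untreated arrays. In the p53 and DNA damage response list 2 of 26 genes rose and 1 fell (fry adjusted p = 0.0262; adjusted p = 0.557 with an estimated correlation): Cdkn1a, the nuclease gene Aen (0.31) and, falling by 0.20, Gtse1. Adjusted over the list alone, 4 rose and 1 fell. Removing any of 5 arrays ended the list's call (adjusted p = 0.06 without C4.7, 0.059 without C3.10, 0.087 without C4.9, 0.061 without C3.4 and 0.14 without C4.1), and removing any of 21 ended that of Aen and any of 6 that of Gtse1. The list's call was also lost with the mean of probe sets (0.092), with only the 2 groups fitted (0.11) and with code B3 (0.26), C3 (0.47) or C4 (0.12) alone. The probe sets of the Y-linked genes Uty (0.62), Kdm5d (0.48) and Eif2s3y (0.30) rose among the 4 genes of the sex check list, from means of 3.04, 2.63 and 2.95 (fry adjusted p = 2.8e-04; adjusted p = 0.0822 with an estimated correlation); Eif2s3y passed no longer without C4.3 (0.061) or C3.2 (0.076). These means, and those of Kdm5d (3.11) and Eif2s3y (3.25) in irradiated arrays, lay under the lower quartile of every array (lowest 3.29), so they do not show that the transcripts were present. Other probe sets differed by 0.04 for Eif2s3y (the one raised at 10.5 months), by 0.40 and 0.13 for Kdm5d and by 0.24, 0.19 and -0.02 for Uty. That list's median turned to -0.03 when the dimmest quartile of genes was left out, which removes all of its Y-linked genes. No immune list was called: the monocyte and macrophage list had a median of 0.04 and a mean of 0.00 (fry adjusted p = 0.996), complement 0.06 (0.797) and the microglia list 0.09 (0.797). Among the study's genes, Glycam1 differed by 0.73 (adjusted p = 0.17), Edn2 by -0.16 (0.85) and Itgam by 0.01 (0.95).

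**Figure D4:**
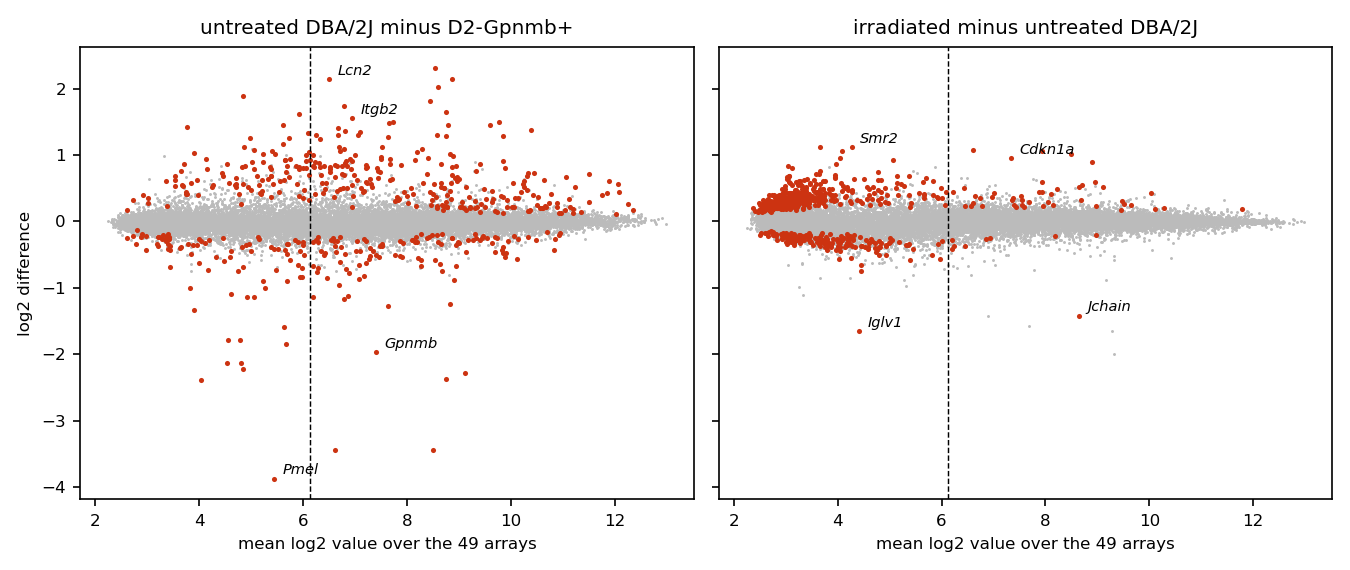
Log2 difference against mean log2 signal of 18193 genes for untreated DBA/2J minus D2-Gpnmb+ and for irradiated minus untreated DBA/2J, both at 8.5 months; red points passed an adjusted p of 0.05 and the dashed line is the median signal. Of the passing genes, 35.2% and 91.9% lay below that median.

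The call set for radiation depended on scaling, on dim genes and on few arrays. With arrays centred on their medians 1204 genes were higher and 88 lower, in place of 473 and 209. Leaving out genes under the median signal left 1 call, Cdkn1a, while leaving out the dimmest quartile left 117. All untreated arrays have codes beginning with B and all irradiated ones codes beginning with C, so radiation and code could not be separated; within codes, the irradiated arrays of C3 alone gave 502 genes, those of C4 alone 15, the untreated arrays of B2 alone 121 and of B3 alone 403, and without C3.2, C4.3 or C3.8 the count was 413, 442 or 448.

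Irradiated DBA/2J was set against D2-Gpnmb+ at 8.5 months to ask which strain differences irradiated mice still show. Lcn2 and Orm1 had the largest rises, and the pigment list was lower. Lcn2 rose 6.97-fold, from 4.39 ± 0.57 (SD, n = 9) to 7.19 ± 0.81 (SD, n = 10), and Orm1 5.65-fold (adjusted p = 1.5e-10, limma). Pmel fell by 3.11 (SE 0.33) and Tyrp1 by 2.42 (SE 0.27), while Gpnmb fell by 2.13 (SE 0.19). In limma 736 genes passed, 394 higher and 342 lower, 228 of them by at least 1.5-fold; with arrays centred on their medians 745 were higher and 139 lower.

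Il7r (2.02), Il1rn (1.97), Cd200r4 (1.77), Rnf128 (1.67), Atp6v0d2 (1.56) and Itgb2 (1.51) rose by amounts near those in untreated DBA/2J, each in 10 of 10 arrays above every control array. Serpina3n, an acute-phase inhibitor of reactive astrocytes, rose by 1.53 (SE 0.21). Il6 differed by 1.76, but its call (adjusted p = 0.046) ended when any of 12 arrays was left out. Mid1, an X-linked ubiquitin ligase gene, fell by 2.35 (SE 0.26), and Car6 (-1.97), Mcoln3 (-1.97), Trpm1 (-1.88), Slc45a2 (-1.78) and Dct (-1.76) were lower as in untreated mice. Of 20 pigment genes 11 fell (13 adjusted over the list alone; fry adjusted p = 4.34e-09; adjusted p = 0.0021 with an estimated correlation). Complement genes rose in 5 of 21 cases (8 adjusted over the list alone), among them Cfi, which cleaves complement fragments, by 0.95. The complement list was called (fry adjusted p = 0.0427, and 0.365 with camera under an estimated correlation). Neither these counts nor this call is independent evidence, as the study picked members of the list from such arrays. In the monocyte and macrophage list 9 of 28 rose and the haemoglobin scavenger receptor Cd163 fell by 1.34 (fry adjusted p = 0.0427; adjusted p = 0.365 with an estimated correlation). The calls of both lists ended when any of 12 arrays was left out, with the 3' minus 5' covariate (adjusted p = 0.07 each) and with code C3 (0.11 and 0.15) or C4 (0.24 each) alone; that of the monocyte list also ended with the mean of probe sets (0.069), and that of Cd163 ended without any of 5.

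Eda2r and Cdkn1a, both p53 targets, rose by 1.07 (SE 0.23) and 0.70 (SE 0.16) against D2-Gpnmb+, and 4 of 26 genes of the p53 list passed (fry adjusted p = 0.0848). With code C3 or C4 alone Cdkn1a had an adjusted p of 0.052 or 0.06. Glycam1 rose by 1.38 (adjusted p = 0.015; 0.096 with code C3 alone and 0.083 with C4 alone), Edn2 differed by 0.33 (0.66) and Itgam by 0.01 (0.97). The sex check list was higher (fry adjusted p = 0.00773, and 0.219 with camera under an estimated correlation). Its fry adjusted p was 0.077 with code C4 alone and 0.84 without the dimmest quartile of genes. In this list Uty was called at 0.59, from a mean near background (3.07). The other probe sets of Uty differed by 0.20, 0.14 and -0.06, and none was called (lowest adjusted p = 0.17 over probe sets, limma). A rise of the Uty transcript was therefore not shown. The number of genes depended on the irradiated arrays used: 362 with code C3 alone and 155 with C4 alone. It was 452 without control array B1.3 and 457 without B1.4.

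Of the 509 genes that differed between untreated DBA/2J and D2-Gpnmb+, 304 also passed in irradiated DBA/2J, 212 higher and 92 lower in both, and 98.8% had the same sign there. If the calls were independent, 6.7 shared higher and 3.7 shared lower genes would be expected; both comparisons use the same 9 control arrays, which raises such counts. Across genes, which are not independent replicates, the log2 differences of these comparisons correlated with r = 0.719. The mean r was 0.608 in simulated unchanged groups with the same shared controls (range 0.394 to 0.852). It was 0.476 when the controls were divided between them. Simulated groups hold no true differences, so their r cannot be set directly against a measured one. The covariance was 0.0271, against means of 0.00722 in simulation and 0.0209 with divided controls. Of the 509 genes, 24 also passed between irradiated and untreated DBA/2J: 19 were lower in DBA/2J and higher after radiation (5.1 if independent), 5 were higher and then lower (3.6 if independent), and none moved the same way (8.1 higher and 2.3 lower if independent). Because these comparisons share the untreated arrays with opposite signs, such counts show little by themselves: for genes called with 10 of the untreated arrays, the radiation difference from the other 10 had the opposite sign in a median of 57.3% (range 25 to 83.9 over 100 divisions). For the strain and radiation effects r was -0.258. Sharing the untreated arrays alone gave a mean of -0.293 in simulation (range -0.698 to 0.398), again without true differences. Dividing those arrays into non-overlapping sets of 10 gave a mean of -0.116 (range -0.241 to 0.07 over 100 divisions, 94 of them below 0). The covariance was -0.007, against means of -0.00274 in simulation and -0.00344 with divided arrays. The simulated covariance was thus smaller in size than the measured one. The divisions reuse the same arrays and are not independent.

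Irradiated DBA/2J mice were compared between 10.5 and 8.5 months for change with age. The older arrays all have code C5 and the younger ones C3 or C4, so age and code could not be separated. In limma 1 gene passed, the Y-linked histone demethylase gene Kdm5d, which rose from 3.11 ± 0.31 to 4.80 ± 0.58 (SD, n = 10 each; at least 3.24-fold, adjusted p = 4.4e-12), in 10 of 10 arrays above every younger array. The 8.5-month means of Kdm5d and of the Eif2s3y probe set (2.41) lay under the lower quartile of every array (lowest 3.29), so their rises are lower bounds. The other 2 probe sets of Kdm5d differed by -0.06 and -0.15. For Eif2s3y, the probe set at 5.92 rose by at least 3.51 (SE 0.15) and the gene's brighter one differed by 0.16. The sex check list was the 1 list of 41 called (fry adjusted p = 3.3e-06; adjusted p = 5.6e-04 with an estimated correlation), and Xist differed by 0.02. No gene passed once the dimmest quartile, which holds Kdm5d, was left out (limma), and 1112 of all genes had an unadjusted p under 0.05. Among immune genes, complement had a median difference of -0.26 (fry adjusted p = 0.358) and the monocyte and macrophage list -0.19 (0.387). Edn2 differed by 0.84 (adjusted p = 0.72), Gpnmb by -0.41 (0.77), Glycam1 by -0.18 (0.97) and Itgam by 0.06 (0.92).

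The irradiated 10.5-month arrays were also set against D2-Gpnmb+ at 8.5 months. In this secondary comparison age, radiation, strain and name code all differ. Lcn2 rose 9.36-fold (adjusted p = 5.5e-05, limma), from 4.39 ± 0.57 (SD, n = 9) to 7.62 ± 1.53 (SD, n = 10). Pmel fell by 3.44 (SE 0.33), Mlana by 3.06 (SE 0.34) and Gpnmb by 2.54 (SE 0.19). In limma 520 genes passed, 295 higher and 225 lower, and 145 differed by at least 1.5-fold. With arrays centred on their medians 837 were higher and 132 lower, and the total was 166 when the 2 groups were fitted without the other arrays.

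Orm1 (1.83), Il1rn (1.66), Serpina3n (1.62), Il7r (1.51), Rnf128 (1.31) and Cd200r4 (1.3) rose at 10.5 months, as did Cfi by 1.31 (SE 0.23) and Kdm5d by at least 2.06 (SE 0.14). The interferon-inducible gene Slfn4 rose by 1.3, a call that ended when any of 10 arrays was left out. Pigment genes fell in 12 of 20 cases (15 adjusted over the list alone; fry adjusted p = 1.1e-11; adjusted p = 8.6e-05 with an estimated correlation), with Tyrp1 at -3.02, Mcoln3 at -2.29, Trpm1 at -2.19, Slc45a2 at -2.15 and Dct at -2.12, beside Car6 (-2.11) and Mid1 (-2.05). The sex check list was higher, with 3 of 4 genes rising (fry adjusted p = 6.11e-12; adjusted p = 8.6e-05 with an estimated correlation). Edn2 passed at 1.16 (adjusted p = 0.049) and Glycam1 at 1.2 (0.046), but leaving out any of 38 and any of 14 arrays ended these calls; Itgam differed by 0.07 (0.57). The count fell to 285 without B1.3, 313 without B1.4, 330 without C5.8, 339 without B1.2 and 342 without B1.1, and rose to 891 without C5.4.

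Arrays of untreated DBA/2J differed from each other in their interferon genes. The mean of the interferon response list had an SD of 0.55 over the 20 untreated DBA/2J arrays and 0.13 over the 9 D2-Gpnmb+ arrays (exact permutation p = 3.1e-05; adjusted p = 0.0025 over 82 two-sided tests). Against irradiated 8.5-month DBA/2J (SD 0.32) the adjusted p was 0.48 (permutation test). Of the 82 tests this was the only call, and 6 had an unadjusted p under 0.05; by the median absolute deviation none passed (adjusted p = 0.27 for this list). The photoreceptor list had an SD of 0.65 in untreated DBA/2J and 0.59 in D2-Gpnmb+. Skeletal muscle genes had an SD of 0.74 in untreated DBA/2J, where array B3.10 stood at 7.18.

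RNA quality did not differ detectably between the groups. The excess of the 3' over the 5' signal of Actb and Gapdh had group means from 1.38 to 1.45, and none of 10 two-sided permutation tests (exact where a group had 9 arrays) of this excess or of the hybridisation spikes passed after adjustment (lowest adjusted p = 0.70; lowest unadjusted p = 0.10). Within untreated DBA/2J, codes B2 and B3 (10 arrays each) differed in 0 genes in limma, with 866 at an unadjusted p under 0.05. Within irradiated 8.5-month DBA/2J, codes C3 and C4 (5 arrays each) differed in 0 genes, with 624. These small tests cannot show differences between codes of different groups.

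**Figure D5:**
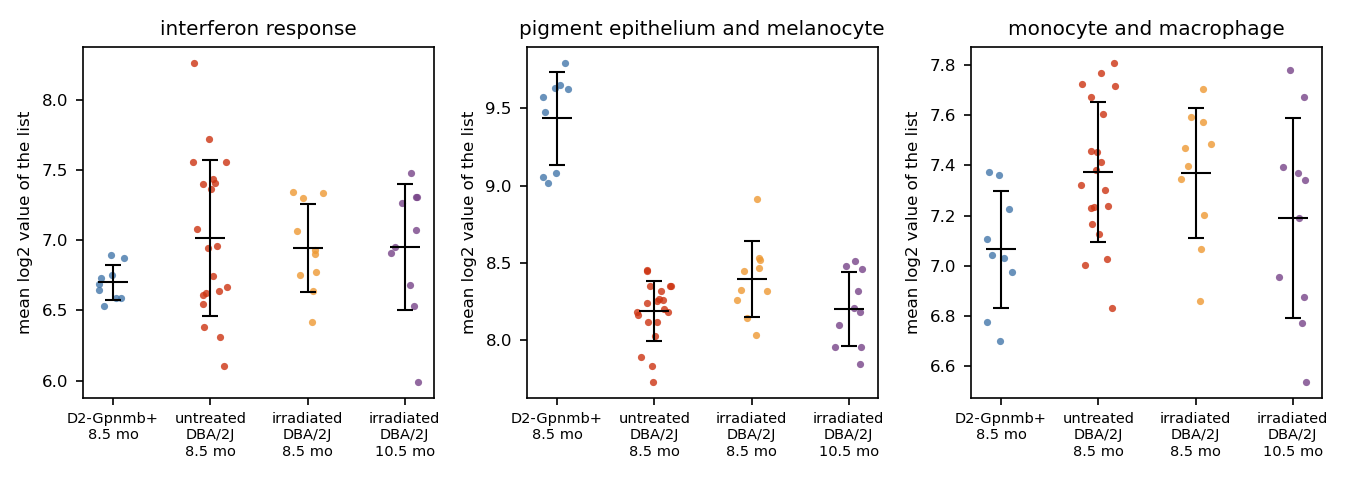
Mean log2 signal of the interferon response, pigment and monocyte and macrophage lists in each array, by group; bars give the mean and SD. Interferon scores of untreated DBA/2J spread more widely (SD 0.55) than those of D2-Gpnmb+ (SD 0.13), while pigment scores separated the strains.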

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

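Of the tests in this part, the next-brightest probe set test and the random splits were written before their results were seen, and all others were chosen only after the pattern was seen. The genes called between irradiated and untreated DBA/2J at 8.5 months were mostly dim. Of the 203 called genes under the median signal that had a further probe set, the next-brightest one differed in the same direction in 65.5% (133 genes; interval 58.7 to 71.7), against 57.9% in uncalled dim genes, 46.3% for a chance direction and 86.8% among dim genes called between the strains, which changed more (median 0.638 against 0.346). This low share fits a shift of dim probe sets between array codes, though it does not exclude true changes. Retina carried into the punch was excluded as the main source, since 675 of the 682 genes stayed called with the photoreceptor covariate. Radiation itself stays open because no name code holds both irradiated and untreated arrays; that 2 of 20 irradiated arrays (C4.7 and C5.4) lay inside the untreated range in the mean of these genes decides nothing, as the genes were picked for this difference.

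A signal in a probe set that the comparisons did not use, Eif2s3y in the irradiated 10.5-month arrays (mean 5.92), was also set against explanations chosen after it was seen. Male animals labelled as female were excluded, because Xist differed by 0.02 from the 8.5-month irradiated arrays (interval -0.12 to 0.16). A general shift of dim probe sets in the 10.5-month arrays was excluded, since the largest rise with age among 9087 dim genes that are not Y-linked was 1.21, against at least 3.51 for this probe set (interval 2.98 to 4.04), which was near background at 8.5 months; a fault of single probe sets was not tested. Male blood-borne cells in female animals fit: over the 10 arrays the signal correlated with the monocyte and macrophage list (r = 0.92, interval 0.70 to 0.98, permutation p = 0.00015, adjusted p = 0.0015 over 10 lists; rho = 0.84, p = 0.0035; r = 0.86 without the 2 farthest arrays). That list has 28 measured genes, and its abundant genes include Lyz1 (12.07), but the fibroblast (0.89), microglia (0.84), endothelium (0.84), T and NK cell (0.82) and skeletal muscle (0.72; 0.08 without the 2 farthest arrays) lists correlated too and the photoreceptor list went the other way (r = -0.61, adjusted p = 0.086; rho = -0.79, adjusted p = 0.018), so the cell type and a difference in the tissue share of the punches stay open.

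Pigment-cell genes were lower in DBA/2J, and the explanations were chosen after that was seen. Less pigment epithelium carried into the DBA/2J punches was excluded as the main source. The 7 genes of the pigment epithelium had a median difference of -0.14 with 0 called. The 10 melanin genes had -2.21 with 10 called (ratio 0.06, interval 0.03 to 0.21). Gpnmb and Slc6a13 (-0.61, SE 0.15, adjusted p = 0.013, limma), which were called lower in the pigment list, are in neither group. The ratio therefore holds only for the genes chosen for these groups. All 7 pigment epithelium genes were lower, from -0.07 (Ttr) to -0.48 (Kcnj13, adjusted p = 0.058, limma). A somewhat smaller share of epithelium was thus not excluded. A shift in 1 code of untreated arrays was excluded, because at least 10 of the 20 list members were called lower with either code (10 with B2, 12 with B3). Against the same controls the pigment list had medians of -0.75 (B2), -0.70 (B3), -0.55 (C3), -0.74 (C4) and -0.71 (C5), so it was lower with each DBA/2J code. The strain as the biological explanation and fewer choroidal melanocytes in the punch were not tested apart.

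Random splits of the arrays, written before their results, asked whether chance could give as many called genes. With the true split counted among 100, only 1 split reached the 509 genes of untreated DBA/2J against D2-Gpnmb+ (highest other 2). The same held for the 682 of irradiated against untreated DBA/2J (highest other 8). It also held for the 736 of irradiated DBA/2J against D2-Gpnmb+ (highest other 101) and the 520 of the 10.5-month arrays against D2-Gpnmb+ (highest other 9). Random sorting of single arrays thus rarely gives such counts. No name code holds arrays of both groups compared, so a difference between codes would pass this test too. For irradiated DBA/2J at 10.5 against 8.5 months 12 of 100 splits reached the 1 gene (highest other 419), so chance was not excluded for that count.

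Single arrays far from the rest of their group were picked out in 9 of 135 sets, where chance alone picks out about 1 in 20. Only the groups of 9 and 10 arrays were searched; in the 20 untreated arrays, which were not, B3.10 stood at 7.18 in skeletal muscle genes (group mean 4.06). In D2-Gpnmb+, array B1.3 was highest in lens crystallins (4.2, nearest 3.99) and B1.8 lowest in ribosomal proteins (10.78, nearest 10.93). In irradiated DBA/2J at 8.5 months, array C4.5 was lowest in MHC class I presentation (8.21, nearest 8.56) and in cell cycle genes (5.25, nearest 5.41). At 10.5 months, array C5.7 was lowest in astrocyte reactivity (7.43, nearest 8.06) and in neuronal injury genes (6.2, nearest 6.56), C5.1 was highest in ganglion cell and axon genes (8.87, nearest 8.6), and C5.2 was highest in lens crystallins (5.12, nearest 4.33) and in skeletal muscle genes (5.88, nearest 3.95).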

How the results depend on the processing

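All settings were fixed before the data were examined except the skeletal muscle covariate and the fit without arrays C4.7 and C5.4, which were chosen after seeing the data. These 2 arrays were picked for lying inside the untreated range in the dim genes called for radiation. Higher counts without them are therefore no test of those calls. Named genes kept their direction and side of the threshold in 14335 of 15325 checks, lost the call in 967 and turned in 23. Lists kept them in 783 of 854, lost the call in 69 and turned in 2. Fits without 1 array, which share most arrays, made up 11662 and 686 of these checks. With single codes named genes kept them in 58 of 104 (B2), 80 of 104 (B3), 69 of 120 (C3) and 44 of 120 (C4). The other settings ran from 158 of 238 (adjusted p under 0.01) to 238 of 238 (array weights and the code as block). Counts stayed within 1.5-fold of 509, 682, 736, 1 and 520, in the order of the report, with quantile normalization repeated, a trended robust variance, the 3' minus 5' covariate and the muscle covariate (503, 597, 694, 1 and 556). Single codes leave fewer arrays by construction; otherwise the cause was not tested. Of the 682 genes, the filter at the median removes 627 by construction, and 1 of the other 55 stayed called. The filter leaves the log2 differences of these 55 genes unchanged. It alters the p-value adjustment and the variance estimate shared across genes, which were not tested apart. Signals near background limit what dim genes can show.

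For untreated DBA/2J against D2-Gpnmb+ (509), the count was 874 with array weights, 968 with the name code as a random block, 286 at an adjusted p under 0.01, 211 at 1.5-fold or more and 211 with code B2 alone. For irradiated against untreated DBA/2J (682) it was 1292 with median-centred arrays, 2709 with every probe set, 117 without the dimmest quartile, 1 without genes under the median, 1194 with the code as block, 226 at an adjusted p under 0.01, 49 at 1.5-fold, 121, 403 and 15 with B2, B3 and C4 alone, and 1028 without C4.7 and C5.4. For irradiated DBA/2J against D2-Gpnmb+ at 8.5 months (736) it was 1655 with every probe set, 270 without genes under the median, 1802 with array weights, 1242 with the block, 208 at an adjusted p under 0.01, 228 at 1.5-fold, and 362 and 155 with C3 and C4 alone. Between 10.5 and 8.5 months (1) it was 2 with the mean of probe sets, 6 with every probe set, 0 without the dimmest quartile, 0 without genes under the median, 2 with the block and 6 with the photoreceptor covariate. At 10.5 months against D2-Gpnmb+ (520) it was 969 with centring, 1260 with every probe set, 326 without the dimmest quartile, 187 without genes under the median, 166 with only the 2 groups, 927 with weights, 1351 with the block, 985 with the photoreceptor covariate, 136 at an adjusted p under 0.01, 145 at 1.5-fold and 963 without C4.7 and C5.4. The code is nested in the groups and its block correlation was -0.029. A negative value narrows the error of the group differences, so calls could hardly be lost. That no named gene lost its call with the block therefore says nothing about effects of the code.

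The 14 list calls became 77 with the preset and 5 with the estimated correlation. The correlation of strain and radiation effects (-0.258) was -0.116 with non-overlapping sets of untreated arrays, and the 1 spread call became 0 with the median absolute deviation. For RNA quality at 10.5 months against D2-Gpnmb+ (0.022), Gapdh alone gave -0.001.

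Directions turned in results that had not passed, and in the sex check list. Itgam in untreated DBA/2J against D2-Gpnmb+ (-0.005) was 0.018 with quantile normalization repeated, 0.004 with the 3' minus 5' covariate and 0.009 with B2 alone. Itgam between irradiated and untreated DBA/2J (0.012) was -0.002 with B2 alone and -0.029 with C4 alone, and against D2-Gpnmb+ (0.007) it was -0.034 with C4 alone. Edn2 between irradiated and untreated DBA/2J (-0.163) was 0.282 with B2 alone. The sex check list there (0.388) was -0.034 without the dimmest quartile and -0.034 without genes under the median, which leaves Xist alone.

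With each array left out in turn, the counts ran from 395 to 584 for untreated DBA/2J against D2-Gpnmb+. They ran from 413 to 963 for irradiated against untreated DBA/2J (413 without C3.2, 442 without C4.3, 448 without C3.8), and from 452 to 971 for irradiated DBA/2J against D2-Gpnmb+ (452 without B1.3, 457 without B1.4). Between ages they were 1 to 2 (2 without C4.9), and at 10.5 months against D2-Gpnmb+ 285 to 891 (285 without B1.3, 313 without B1.4, 330 without C5.8, 339 without B1.2, 342 without B1.1, 891 without C5.4). The correlation ran from -0.284 to -0.211. Itgam ran from -0.022 to 0.032, -0.002 to 0.034 and -0.008 to 0.044 in the 3 comparisons at 8.5 months, Edn2 between irradiated and untreated DBA/2J from -0.292 to -0.04, Glycam1 between ages (-0.181) from -0.403 to 0.037, and the sex check list between irradiated and untreated DBA/2J from 0.351 to 0.432.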

Other observations

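Of a list of neutrophil and mast cell genes that did not pass as a whole, 4 mast cell genes fell in the irradiated 10.5-month arrays against D2-Gpnmb+; they were picked out after their values were seen and no list of mast cells was tested. Mcpt4, a mast cell chymase, fell by 1.54 (SE 0.33, adjusted p = 0.0049, limma), from 6.55 ± 0.60 (SD, n = 9) to 5.01 ± 1.11 (SD, n = 10), and the chymase gene Cma1 fell by 1.52 (SE 0.33). The carboxypeptidase gene Cpa3 fell by 1.16 and the tryptase gene Tpsb2 by 1.05. In the same list of neutrophil and mast cell genes the neutrophil genes Lcn2 and S100a8 rose by 3.23 and 1.00, so 2 of 17 rose and 4 fell (fry adjusted p = 0.879). With only the 2 groups in the fit Mcpt4, Cma1 and Cpa3 lost their call, with an adjusted p of 0.055, 0.078 and 0.13 (limma). Removing any of 5 arrays ended the call of Cpa3. Tpsb2 was not put through the alternative settings. Between 10.5 and 8.5 months Mcpt4 differed by -0.73 (adjusted p = 0.769) and Cma1 by -0.83 (adjusted p = 0.703).

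The submitters' clusters, made from these arrays, were not tested. In untreated DBA/2J the complement list had a median score of 7.62 in cluster Stg1A (n = 4), 7.69 in Stg1B (n = 8) and 7.93 in Stg1C (n = 3), and the monocyte and macrophage list 7.15, 7.35 and 7.72. Interferon response genes had their highest median, 7.44, in the 5 untreated arrays without a cluster, which ran from 6.11 to 8.26.

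A hypothesis of this work, written before its test, was that pigment-cell genes fall as immune genes rise within untreated DBA/2J. Over the 20 untreated arrays the pigment list and the monocyte and macrophage list gave r = 0.27 (interval -0.20 to 0.63, permutation p = 0.26; rho = 0.34, p = 0.14; r = 0.25 without the 2 farthest arrays; 1 test in the family, adjusted p = 0.26). Within codes r was 0.31 (B2) and 0.32 (B3), so the hypothesis was not borne out.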
